A study of Mus musculus with 3 samples.

How the data were processed

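RNA of single cells from normal mouse embryos was measured in 3 libraries, 1 per group, at embryonic day 7.0 (E7.0), E7.25 and E7.5. The E7.5 library holds cells of the posterior region of the embryo. Per the labels, embryos were dissociated with trypsin, passed through a 40 µm strainer and loaded on 1 channel per sample for a target of 10000 cells. The droplet libraries used the 10x Genomics 3' protocol, version 3.0 or 3.1. Which version each library used, how many embryos were pooled and the genome build are not given in the sources used here.

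The deposited files hold counts of unique molecular identifiers (UMIs) per gene and barcode, written by Cell Ranger 6.0.1 per the file headers and filtered to the barcodes that the software called as cells. The authors applied no scaling to these values, which are whole numbers. Of the gene identifiers, 32158 were found in GENCODE mouse release M21 on GRCm38 and 127 were not. Coordinates come from that annotation.

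Cells were kept at 1000 or more detected genes and at most 10% mitochondrial UMIs. Predicted doublets were marked in each library with a reimplementation of the Scrublet score, with 2 simulated doublets per cell and an expected rate of 0.05, and removed. Where the automatic limit marked under 0.5% of cells, the highest scores were marked instead, at 0.8% per 1000 cells. This second rule applied to E7.5 posterior, where the automatic limit marked 8 cells and the second rule 570. In the alternative of at most 5% mitochondrial UMIs it applied to all 3 libraries. It then marked 457 cells at E7.0 and 170 at E7.25, in place of 160 and 216. Values at the 5% limit thus reflect both changes. In 2100 cells per library of simulated data, the automatic limit marked 9, 39 and 5 of 100 planted doublets at E7.0, E7.25 and E7.5 posterior. Of the 100 highest scores, 55, 62 and 56 were planted doublets. Doublets therefore remain among the kept cells.

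Counts were scaled to 10000 per cell and log transformed after adding 1. The 2000 most variable genes, chosen per library and combined, gave 30 principal components. A graph of 15 neighbours was clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 0), with the 3 libraries together and without integration, into 22 clusters. A cluster took the name of the class with the most markers among its top 100 genes by fold over the other clusters, with at least 3 markers required. There were 21 classes with fixed markers. Genes under 30 CPM were not used in naming, 5 CPM were added to both sides of each ratio, and a marker whose detection differed by less than 1.5 times between clusters was left out. A cluster with under 1/3 of the depth of its own libraries and no marker of the class among its top 10 genes was left unnamed. Class names are therefore given as likenesses. Epiblast-like, caudal epiblast-like and streak-like clusters were joined into a single class after the data were examined, because their limits moved with the settings.

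Raw UMI counts were summed over the kept cells of a library, or over those of a class with at least 100 cells in both libraries, and scaled to a common total over all genes (CPM). Ratios are log2 of CPM. With 1 library per group no test was run and no spread between embryos is known. Each value has an exact 95% interval: Poisson for a sum, conditional binomial for a ratio and Clopper-Pearson for a share. These intervals cover counting error only. A gene with 3 UMIs or fewer in a library would be given as a bound against 3 UMIs.

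There were 24 fixed gene lists. They cover pluripotency and epiblast, primitive streak, epithelial, mesenchymal transition, mesoderm regulators, Hox and Cdx, anterior identity, haemato-endothelial, primitive blood, visceral endoderm and trophoblast genes. They also cover the WNT, NODAL, BMP, FGF, retinoic acid and NOTCH pathways, glycolysis, oxidative phosphorylation, S phase, G2 and M phase, imprinted genes, immediate early and heat shock genes, and hypoxia and apoptosis. Members at 20 CPM or more in at least 1 of the libraries compared were measured. With 5 or more such members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. That percentile describes these libraries and is not a test. The genes named are these members and, among genes at 50 CPM or more, the 12 highest and 12 lowest ratios between whole libraries and the 8 highest and 8 lowest within a class. Mitochondrial, ribosomal protein, Gm, Rik, Xist, Tsix and Y-linked genes were left out of the ranking.

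The share of cells with a UMI of a gene was taken after thinning each cell to 5000 UMIs, with shallower cells left out, and is given beside the same share in visceral endoderm-like cells, which should lack the gene. Sex was read from Xist and 4 Y-linked genes at 1 UMI or more.

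The filters, clustering settings, doublet rules, marker and gene lists, comparisons and the rule for named genes were chosen before the data were examined. The limits used in naming clusters were set afterwards. The alternatives were other limits on detected genes (500 and 2000) and mitochondrial UMIs (5%), doublets kept, resolutions 0.5 and 2, 4000 variable genes, 50 principal components and each library clustered by itself. They also included cell cycle genes left out, cells thinned before clustering, scaling by TMM factors, CPM without mitochondrial and ribosomal protein genes and Malat1, a mean over cells, no minimum for list members, thinning to 3000 UMIs and 2 UMIs for a sex call. A further 4 were added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9.

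The ratios were tested on simulated data for each comparison, with counts drawn at the depth of these libraries. For E7.25 against E7.0, 100 of 100 genes changed 2-fold and 100 of 100 changed 4-fold came within 1.25 times of their fold, among 5201 genes. The same counts held for E7.5 posterior against E7.25, among 5273 genes, and against E7.0, among 5051 genes. The intervals held the true ratio for 95.1%, 95.4% and 95.5% of genes. Of 200 lists of unchanged genes, 6, 5 and 7 fell under the percentile 2.5 or over 97.5. Of 50 lists with 0.5 added to each log2 ratio, 50 fell over 97.5 in each comparison. Both simulated libraries were drawn from a shared mean, so apart from the changed genes they differed by counting error only. These checks therefore cover the calculation and not how percentiles behave where libraries differ in their cells.

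Named genes and lists within visceral endoderm-like cells are left out, since they moved strongly with the limit on mitochondrial UMIs. Shares of nascent and paraxial mesoderm-like cells are left out because the clusters that carried these names differed between libraries. Results for a few genes are not reported here.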

Results

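Single cells of normal mouse embryos of the ARC strain were profiled during gastrulation, when epiblast cells enter the primitive streak and leave it as mesoderm and endoderm. The labels name the embryo at E7.0 and E7.25 and the posterior region of the embryo at E7.5. Each group is 1 library, so stage and library cannot be separated, and at E7.5 the dissected region moves with them. The files held 10232 barcodes and 111010034 UMIs at E7.0, 6173 barcodes and 48836272 UMIs at E7.25, and 11468 barcodes and 92190474 UMIs at E7.5 posterior. After filters and removal of predicted doublets, 7781, 4978 and 7868 cells remained, with 104389610, 44144846 and 77568027 UMIs. The median kept cell had 11167, 8159 and 9005 UMIs and 3065, 2673 and 2715 detected genes. Mitochondrial UMIs made up a median of 2.26%, 2.38% and 3.42% of a cell.

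The classes of cells show which tissues each dissection captured. Epiblast-like cells are the pluripotent source of the embryo, and caudal epiblast-like cells at its posterior end feed the trunk. Epiblast and streak-like cells made up 34.2% of cells at E7.0 (95% Clopper-Pearson interval 33.2 to 35.3), 33.6% at E7.25 (32.3 to 35.0) and 47.4% at E7.5 posterior (46.2 to 48.5). The order of the libraries rested on the settings: with at least 500 detected genes the shares were 30.4%, 30.8% and 18.8%, and with 50 principal components 44.4%, 31.1% and 45.6%. Mesoderm-like cells made up 35.6% (34.6 to 36.7), 36.1% (34.7 to 37.4) and 35.9% (34.8 to 37.0). Different clusters held most of these classes in each library. Epiblast and streak-like cells lay mainly in clusters 1 and 9 at E7.0, in cluster 2 at E7.25 and in clusters 0 and 6 at E7.5 posterior. Mesoderm-like cells lay mainly in clusters 3 and 4 at E7.0, in 10, 8 and 11 at E7.25 and in 5, 11 and 8 at E7.5 posterior. A cluster that is mostly 1 library may be that library rather than a cell type.

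Within the joined class, caudal epiblast-like cells made up 31.4% of the E7.5 posterior library, 0.398% at E7.0 and 0.824% at E7.25. This cluster was almost wholly from the library of dissected posterior tissue. No cluster took this name with at least 2000 detected genes, at a limit of 5% mitochondrial UMIs or with each library clustered by itself. With at least 500 detected genes the caudal epiblast-like cells were unnamed, and the joined class fell to 18.8% at E7.5 posterior. Streak-like cells made up 12.3% at E7.0, 0.141% at E7.25 and 0.394% at E7.5 posterior. With each library clustered by itself the streak-like shares were 10.7%, 8.80% and 8.58%. With at least 2000 detected genes they were 18.2%, 0.493% and 19.7%, and at a limit of 5% mitochondrial UMIs 11.6%, 0.832% and 18.1%, higher at E7.5 posterior than at E7.0. The E7.0 share lay above the E7.25 share in each of these settings. The size of that difference and the place of E7.5 posterior rested on the clustering and the filters. Extraembryonic mesoderm-like cells, the source of the allantois and the yolk sac mesoderm, made up 1.40%, 10.9% and 6.56%. At E7.25 they include the cluster of highest UMI count, 96 cells (1.93%) found only in that library. Its top 10 genes held 1 marker of this class and 1 of trophoblast. The other cluster of this name held 8.98% at E7.25. Haemato-endothelial-like cells, which form the first blood and vessels, made up 0.681%, 2.65% and 0.813%. Outside the embryo proper, visceral endoderm-like cells made up 12.1% (11.4 to 12.9), 17.9% (16.8 to 18.97) and 7.16% (6.60 to 7.75). At a limit of 5% mitochondrial UMIs they were 8.80%, 11.3% and 2.62%, and with at least 2000 detected genes 7.38%, 15.002% and 3.97%. Trophoblast-like cells made up 1.39% (1.14 to 1.67), 5.71% (5.08 to 6.39) and 0.140% (0.070 to 0.250), the last from 11 cells. Definitive endoderm and gut-like cells made up 9.45% (8.81 to 10.1), 3.64% (3.13 to 4.19) and 3.101% (2.73 to 3.51). With each library clustered by itself they were 12.1%, 6.95% and 5.11%, and with at least 2000 detected genes 12.99%, 5.91% and 5.31%. Node and notochord-like cells made up 3.28%, 1.49% and 2.94%. An unnamed cluster with few mitochondrial UMIs held 3.88%, 1.61% and 3.43% of cells.

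**Figure D1:**
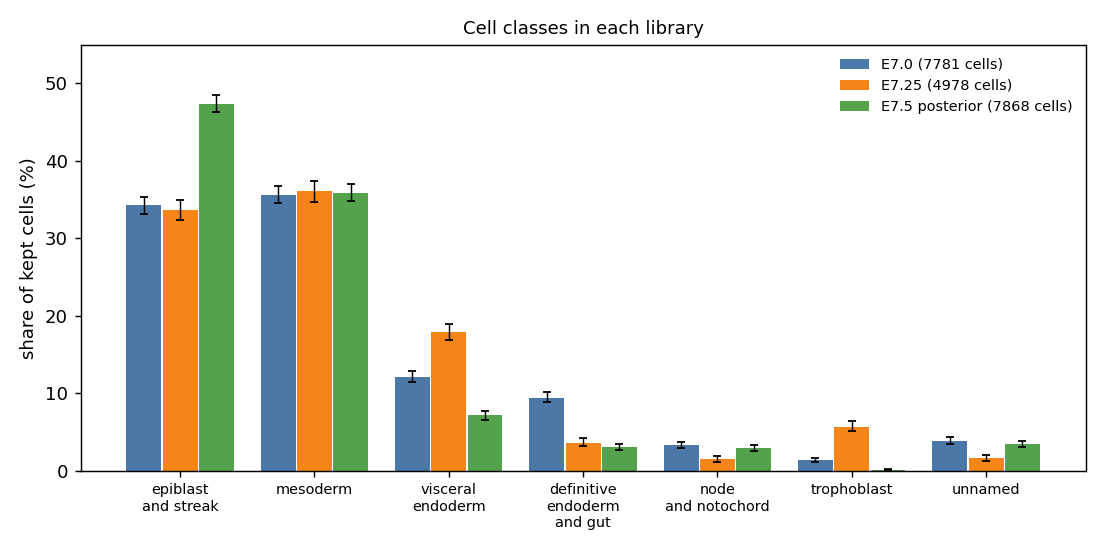
Share of kept cells in each class (percent, vertical axis) for the E7.0, E7.25 and E7.5 posterior libraries, with 95% Clopper-Pearson intervals as bars. Mesoderm-like shares lie between 35.6% and 36.1%, and the visceral endoderm-like share is highest at E7.25 (17.9%).

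E7.25 against E7.0 asks how gastrulating embryos of 2 close stages differ. The primitive streak and anterior identity lists were lower at E7.25. The visceral endoderm list was higher, beside a larger share of visceral endoderm-like cells, and so were Bmp4, Id2 and Hand1. Lhx1, a homeobox gene of the anterior streak and head organiser (ENSMUSG00000018698, chromosome 11, 84518284 to 84525535 on GRCm38), stood at 62.4 CPM at E7.25 and 430.3 CPM at E7.0 (log2 ratio -2.79, 95% interval -2.84 to -2.73). Tdgf1, the NODAL co-receptor Cripto (ENSMUSG00000032494, chromosome 9, 110939603 to 110946158), stood at 44.9 and 255.6 CPM (-2.51, -2.58 to -2.44). Bmp4, which patterns posterior and extraembryonic mesoderm (ENSMUSG00000021835, chromosome 14, 46383520 to 46390669), stood at 51.5 and 10.4 CPM (2.31, 2.20 to 2.41). The BMP target Id2 stood at 127 and 26.7 CPM, and Hand1, a regulator of extraembryonic mesoderm, at 101.3 and 23.95 CPM. With TMM factors all log2 ratios of this comparison shift by -0.24.

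The primitive streak list had 9 measured members, with 6 at least 2-fold lower at E7.25, 0 at least 2-fold higher and 3 within 2-fold (median log2 ratio -1.29, under all of the 10000 random lists). Gsc, a marker of the anterior streak, stood at 3.90 and 42.7 CPM, Fgf8 at 15.5 and 100.5 CPM, Eomes at 45.1 and 154 CPM, and Mixl1 at 20.6 and 50.4 CPM. Brachyury (T), which marks the whole streak, went the other way, at 143 and 98.5 CPM. The list of anterior identity genes (6 members, 2 lower and 4 within) had a median of -0.93, and the NODAL list (5 members, 2 lower and 3 within) of -0.90, with Lefty2 at 47.9 and 138 CPM. The FGF list (10 members, 2 lower and 8 within) had a median of -0.30, with Fgf5 at 21.6 and 74.9 CPM. The pluripotency list (13 members, 2 lower and 11 within) stood at -0.24, the WNT list (8 members) at -0.23 and the mesenchymal transition list (7 members) at -0.21. In the retinoic acid list Cyp26a1, which degrades retinoic acid, stood at 28.0 and 116 CPM while Crabp1 stood at 98.7 and 43.0 CPM. Of 2 measured NOTCH members, Hes1 stood at 23.9 and 92.9 CPM. Fgf8, Sp5, Hes1 and Dll3 are among 96 genes that were lower at E7.25 than in both other libraries in 4 classes of cells. These 96 genes had a median transcript length of 1308 bases, against 3222 for all genes tested.

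The visceral endoderm list had 15 measured members, 8 of them at least 2-fold higher at E7.25 and 7 within 2-fold, with a median log2 ratio of 1.01. Its Ttr stood at 838 and 408 CPM, Apoa4 at 110 and 37.7 CPM and Apoc2 at 985 and 374 CPM. Without visceral endoderm-like and trophoblast-like cells the median was 1.92, so these transcripts also differed in the other cells. H19, Apoa2, Apoa4 and Apoc2 are among 61 genes higher at E7.25 than in both other libraries in 4 classes. The imprinted list (12 members, 3 higher and 9 within) had a median of 0.63, with H19, a noncoding growth-related RNA, at 916 and 206 CPM, Igf2 at 51.0 and 18.9 CPM and Peg10 at 113 and 45.3 CPM. The BMP list (7 members, 2 higher and 5 within) stood at 0.47 and the epithelial list (9 members, 1 higher and 8 within) at 0.38, with Krt19 at 39.4 and 13.7 CPM. Immediate early and heat shock genes (9 members, 4 higher and 5 within) stood at 0.48, with Fos at 33.4 and 6.18 CPM and Egr1 at 33.7 and 8.12 CPM. Such genes also respond to dissociation of tissue. Glycolysis genes (15 members, 1 higher, 1 lower and 13 within) stood at 0.33 and the hypoxia and apoptosis list (6 members) at 0.24. Of mesoderm regulators (9 members), Hand1 and Foxf1 were at least 2-fold higher, Mesp1 (292 and 606 CPM) and Lefty2 were at least 2-fold lower, and 5 were within 2-fold, with a median of 0.02. Cdx2 (43.3 and 10.96 CPM) and Hoxb1 (30.7 and 8.92 CPM) were both higher at E7.25. Trophoblast-like cells, which also express Cdx2, made up 5.71% of cells at E7.25 and 1.39% at E7.0. The blood gene Smim1 (30.2 and 11.9 CPM) was higher at E7.25, and the 3 measured haemato-endothelial genes were within 2-fold. Oxidative phosphorylation genes stood at 0.12, S phase genes at 0.01 and G2 and M phase genes at -0.10, and the median of all genes was 0.12.

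**Figure D2:**
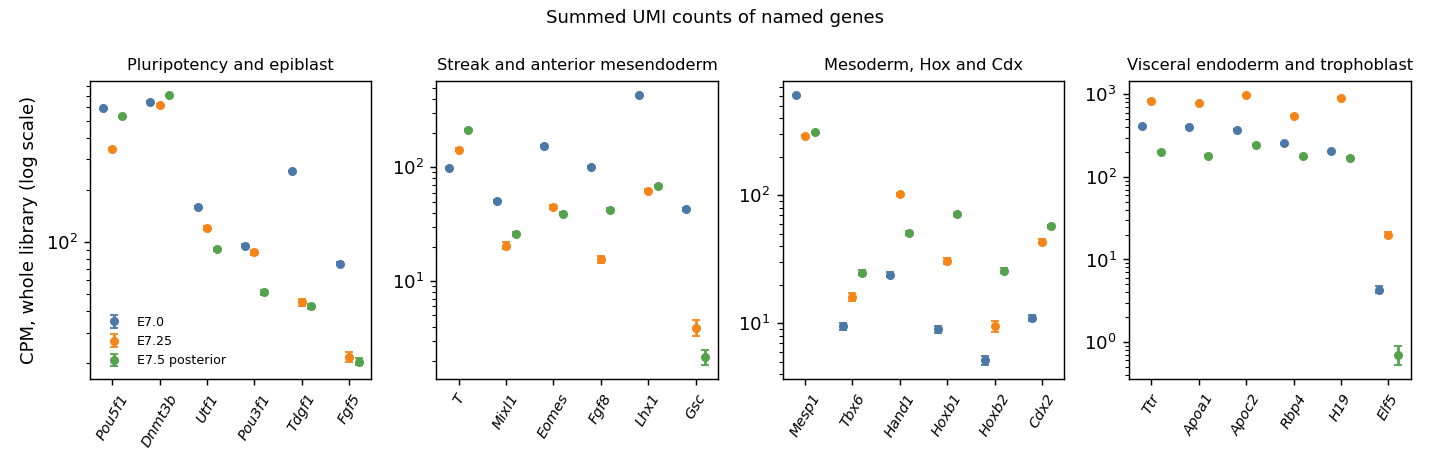
CPM of named genes in the summed E7.0, E7.25 and E7.5 posterior libraries (logarithmic axis), with exact Poisson intervals as bars where they exceed the symbols. Lhx1 and Tdgf1 are highest at E7.0, and Hoxb1 and Cdx2 are highest at E7.5 posterior.

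Cells of a like class were also compared, although the clusters within a class differed between libraries. In epiblast and streak-like cells, E7.25 against E7.0, the streak list (7 members, 4 lower and 3 within) had a median of -1.79. The streak-like cluster made up 36.0% of this class at E7.0 and 0.4% at E7.25, so this median also reflects the makeup of the class. Tdgf1 stood at 16.0 and 135 CPM, Fgf8 at 21.3 and 124 CPM, Eomes at 42.7 and 147 CPM and Lhx1 at 3.58 and 65.2 CPM. With each library clustered by itself the streak median was -0.64, and Lhx1 had a log2 ratio of -1.39 in place of -4.19, and Tdgf1 of -1.90 in place of -3.08. The naive and formative marker genes Nanog (13.8 and 29.5 CPM) and Foxd3 (4.06 and 20.8 CPM) were lower at E7.25, while Sox2 stood at 92.8 and 60.1 CPM. The pluripotency list (15 members, 4 lower and 11 within) had a median of -0.38. The neural and caudal ectoderm gene Irx3 was higher at E7.25 (59.8 and 13.7 CPM), as were Id2 (71.3 and 23.1 CPM) and Jun (107 and 34.3 CPM).

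In mesoderm-like cells, E7.25 against E7.0, the BMP list (9 members, 2 higher and 7 within) had a median of 0.80, with Bmp4 at 102 and 17.1 CPM and Id2 at 50.6 and 6.20 CPM. All 13 measured imprinted genes had ratios above 0 (median 0.92), among them H19 (394 and 57.7 CPM), Mest (157 and 71.4 CPM) and Igf2 (42.1 and 10.2 CPM). Hand1 (213 and 55.7 CPM), Foxf1 (51.3 and 20.8 CPM) and Ahnak (70.3 and 5.99 CPM) were higher, beside the larger share of extraembryonic mesoderm-like cells. The streak list (10 members, 5 lower and 5 within) had a median of -0.98, or -1.89 at resolution 2 and -1.85 with each library clustered by itself. Mesp1, expressed as cells leave the streak, stood at 693 and 1477 CPM. Lhx1 (100.4 and 672 CPM), Tdgf1 (86.9 and 436 CPM), Eomes (41.1 and 181 CPM) and Cyp26a1 (32.0 and 173 CPM) were lower. Cdx2 was higher (45.8 and 5.40 CPM). The visceral endoderm list (8 members, all higher) had a median of 2.48, and the epithelial list (6 members, 4 higher) of 1.93, with Krt18 at 346 and 48.1 CPM. A cluster of 96 cells of E7.25, counted as extraembryonic mesoderm-like, had a median of 27241 UMIs per cell. Without it the visceral endoderm median was 1.05.

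E7.5 posterior against E7.25 sets posterior tissue beside the slightly younger embryo. Most members of the visceral endoderm list were at least 2-fold lower in the posterior library. Hoxb1, a Hox gene expressed early and caudally (ENSMUSG00000018973, chromosome 11, 96365752 to 96368256), stood at 70.6 and 30.7 CPM, and its neighbour Hoxb2 at 25.7 and 9.47 CPM, while Cdx2 was within 2-fold (57.1 and 43.3 CPM). Trophoblast-like cells, which also express Cdx2, made up 0.140% of cells at E7.5 posterior and 5.71% at E7.25. Aldh1a2, which makes retinoic acid (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243), stood at 21.7 and 5.28 CPM, and the binding protein Crabp2 at 33.9 and 15.9 CPM. The retinoic acid list (5 members, 2 higher and 3 within) had a median of 0.88, and of -0.08 with no minimum on CPM. The NOTCH list (5 members, 2 higher and 3 within) had a median of 0.78, over all random lists, with the segmentation genes Hes7 (24.7 and 8.495 CPM) and Dll1 (27.1 and 11.7 CPM). Of its members, 2 (Hes1 and Dll3) are among the 96 genes lower at E7.25 in 4 classes. The WNT list (9 members, 1 higher and 8 within) had a median of 0.54, with Sp8 at least 2-fold higher, Axin2 at 38.5 and 26.0 CPM and brachyury (T) at 211 and 143 CPM. The streak list (6 members, 1 higher and 5 within) had a median of 0.58, with Fgf8 at 42.4 and 15.5 CPM. Fgf8 and Sp5 of the streak list, and Sp5 of the WNT list, are also among those 96 genes. With TMM factors all ratios of this comparison shift by 0.11.

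Of 15 visceral endoderm genes, 13 were at least 2-fold lower at E7.5 posterior and 2 were within 2-fold (median -1.71), with Ttr at 202 and 838 CPM, Apoa1 at 181 and 788 CPM and Apob at 90.5 and 330 CPM. At a limit of 5% mitochondrial UMIs the median was -3.10, with visceral endoderm-like shares of 2.62% and 11.3%, and without visceral endoderm-like and trophoblast-like cells it was -2.70. The BMP list (6 members, 2 lower and 4 within) had a median of -0.87, with Bmp4 at 17.2 and 51.5 CPM and Id2 at 51.6 and 127 CPM. The epithelial list (9 members, 2 lower and 7 within) stood at -0.64 and mesoderm regulators (10 members, 3 lower and 7 within) at -0.39, or at 0.08 with no minimum on CPM. Hand1 (50.6 and 101.3 CPM), Gata4 (13.0 and 31.7 CPM) and Tbx3 (13.1 and 30.3 CPM) were lower. The imprinted list (12 members, 3 lower and 9 within) stood at -0.34, with H19 at 171 and 916 CPM (log2 ratio -2.42, or -3.06 at the 5% limit), and the immediate early and heat shock list (9 members) at -0.33. Smim1 (11.2 and 30.2 CPM) was lower, and the 3 haemato-endothelial genes were within 2-fold. The other lists stood nearer 0: pluripotency (-0.08), anterior identity (-0.02), NODAL (-0.08), FGF (-0.14), mesenchymal transition (0.19), hypoxia and apoptosis (0.21), glycolysis (-0.19), oxidative phosphorylation (-0.13), S phase (0.16) and G2 and M phase (0.05). Of the 12 genes with the highest ratios, 11 are among the 96 genes lower at E7.25 in 4 classes, such as Eno1 (1118 and 456 CPM), Stmn1 (539 and 222 CPM) and Hmga1 (106 and 34.3 CPM).

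In mesoderm-like cells, E7.5 posterior against E7.25, retinoic acid genes (5 members, 2 higher and 3 within) had a median of 0.83, with Aldh1a2 at 47.6 and 10.97 CPM. NOTCH genes (6 members, 2 higher and 4 within) had a median of 0.73, with Dll1 at 62.3 and 25.8 CPM and Hes7 at 35.4 and 14.6 CPM. Of the Hox and Cdx list, Hoxb1 (138 and 62.8 CPM) and Hoxb2 (53.2 and 20.9 CPM) were higher and Cdx2 was within 2-fold. Foxc1, a gene of paraxial mesoderm, stood at 30.9 and 15.7 CPM, while Etv2, a regulator of blood and endothelium, stood at 34.5 and 65.6 CPM. Visceral endoderm genes (8 members, 7 lower) had a median of -3.37, or -1.51 without the cluster of 96 deep cells. In epiblast and streak-like cells the WNT list (7 members, 1 higher and 6 within) had a median of 0.57 and the pluripotency list (12 members, all within 2-fold) of -0.46. The pluripotency median was 0.03 at a minimum of 500 detected genes, where the caudal epiblast-like cells were unnamed.

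E7.5 posterior against E7.0 spans the series. It sets the early embryo, with its anterior streak, beside posterior tissue whose cells express the early Hox genes. Hoxb1 stood at 70.6 and 8.92 CPM (log2 ratio 2.98, 95% interval 2.88 to 3.09). Cdx2, a regulator of Hox genes and axis elongation (ENSMUSG00000029646, chromosome 5, 147300805 to 147307270), stood at 57.1 and 10.96 CPM (2.38, 2.29 to 2.48). Without visceral endoderm-like and trophoblast-like cells, of which the latter also express Cdx2, its log2 ratio was 3.36. Hoxb2 stood at 25.7 and 5.11 CPM, so that all 3 measured Hox and Cdx members were at least 2-fold higher. Brachyury (ENSMUSG00000062327, chromosome 17, 8434423 to 8442496) stood at 211 and 98.5 CPM (1.10, 1.07 to 1.14). Lhx1 stood at 68.6 and 430.3 CPM (-2.65, -2.69 to -2.61) and Tdgf1 at 42.6 and 255.6 CPM (-2.59, -2.64 to -2.53).

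The pluripotency list (13 members, 3 lower and 10 within) had a median of -0.64, under all random lists, with Fgf5 at 20.4 and 74.9 CPM, Zic2 at 26.5 and 61.6 CPM and Pou5f1 within 2-fold (532 and 593 CPM). The streak list (9 members, 1 higher, 4 lower and 4 within) had a median of -0.95, with Gsc at 2.14 and 42.7 CPM, Eomes at 39.2 and 154 CPM and Wnt3 at 10.5 and 24.8 CPM. The NODAL list (5 members, 1 lower and 4 within) stood at -0.86, the anterior list (6 members, 2 lower and 4 within) at -0.83 and the FGF list (10 members, 2 lower and 8 within) at -0.48. The NOTCH list (5 members, 3 higher, 1 lower and 1 within) stood at 1.002, with Hes7 at 24.7 and 5.84 CPM and Notch1 at 28.1 and 14.0 CPM. The retinoic acid list (5 members, 2 higher, 1 lower and 2 within) stood at 0.73, with Aldh1a2 at 21.7 and 0.297 CPM and Cyp26a1 at 26.5 and 116 CPM. The WNT list (10 members, 2 higher, 1 lower and 7 within) stood at 0.26. Mesoderm regulators (8 members, 2 higher, 1 lower and 5 within) stood at -0.85, or 0.45 with no minimum on CPM, with Tbx6 (24.8 and 9.49 CPM) and Hand1 (50.6 and 23.95 CPM) higher and Gata6 (19.4 and 41.9 CPM) lower. The visceral endoderm list (12 members, 2 lower and 10 within) stood at -0.81, or -2.59 at a limit of 5% mitochondrial UMIs. The imprinted list (11 members, 1 higher and 10 within) stood at 0.32, with Phlda2 at 835 and 412 CPM. Of 12 genes with the lowest ratios, several code for histones, such as Hist1h1b (106 and 437 CPM). Epithelial (-0.17), mesenchymal transition (-0.21), BMP (0.23), glycolysis (0.20), oxidative phosphorylation (0.08), S phase (0.17), G2 and M phase (0.03), immediate early and heat shock (0.20) and hypoxia and apoptosis (0.22) genes stood closer to 0. No primitive blood or trophoblast gene reached the minimum, and the 3 haemato-endothelial genes were within 2-fold.

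In epiblast and streak-like cells, E7.5 posterior against E7.0, pluripotency genes (15 members, 6 lower and 9 within) had a median of -0.66. The primitive streak list (7 members, 1 higher, 4 lower and 2 within) had a median of -1.20, with -2.20 to -0.69 over the alternatives. Here too the makeup differed, with the streak-like cluster at 0.8% of the class at E7.5 posterior and 36.0% at E7.0. Utf1 (167 and 353 CPM), Pou3f1 (91.8 and 209 CPM), Fgf5 (23.0 and 95.5 CPM) and Tdgf1 (13.4 and 135 CPM) were lower. The log2 ratio of Tdgf1 was -3.33, or -1.92 at resolution 2 and -2.74 with each library clustered by itself. Cdx2 (72.1 and 6.89 CPM), Foxb1 (59.2 and 8.41 CPM), Meis2 (75.5 and 23.3 CPM) and brachyury (T) (161 and 50.5 CPM) were higher. The WNT list (7 members, 3 higher and 4 within) had a median of 0.51, or -1.95 with at least 500 detected genes, with Sp8 (34.6 and 11.1 CPM) and Nkd1 (27.1 and 12.2 CPM) higher. These ratios rest on the caudal epiblast-like cluster: at a minimum of 500 detected genes it lost its name, and the log2 ratios were -0.46 for Cdx2, -0.36 for Meis2, -1.95 for brachyury (T) and 1.56 for Foxb1. With each library clustered by itself those of Cdx2, Meis2 and brachyury (T) were 2.74, 0.99 and 0.93, and with doublets kept that of brachyury (T) was 0.80.

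In mesoderm-like cells, E7.5 posterior against E7.0, genes of the Hox and Cdx list were higher, with Hoxb1 at 138 and 21.8 CPM, Hoxb2 at 53.2 and 12.8 CPM and Cdx2 at 37.5 and 5.40 CPM. Of 14 mesoderm regulators, 6 were higher and 8 within 2-fold. The higher ones were the paraxial and segmental genes Tbx6 (53.4 and 23.2 CPM), Tcf15 (23.9 and 8.25 CPM), Foxc1 (30.9 and 13.6 CPM) and Foxc2 (45.7 and 22.5 CPM), with Hand1 (123 and 55.7 CPM) and Foxf1 (45.8 and 20.8 CPM). Tbx6 had a log2 ratio of 1.20, or 0.53 at resolution 2. The retinoic acid list (5 members, 2 higher, 1 lower and 2 within) had a median of 0.80, with Aldh1a2 at 47.6 and 0.493 CPM. The imprinted list (11 members, 3 higher and 8 within) stood at 0.55 and the BMP list (8 members, 2 higher and 6 within) at 0.36. The NOTCH list (6 members, 2 higher and 4 within) stood at 0.35, or -0.19 at resolution 2. The streak list (10 members, 3 lower and 7 within) stood at -0.69, or -1.35 at resolution 2, and the anterior list (5 members, 2 lower and 3 within) at -0.97. Lhx1 (131 and 672 CPM), Eomes (41.2 and 181 CPM) and Cyp26a1 (44.4 and 173 CPM) were lower.

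Counting cells at equal depth shows how widely a gene was detected. At 5000 UMIs per cell, Hoxb1 was detected in 8.24% of mesoderm-like cells at E7.0, 22.0% at E7.25 and 38.1% at E7.5 posterior, against 0.26%, 0.14% and 1.76% of visceral endoderm-like cells. Not thinned, the shares were 17.5%, 32.3% and 50.4%, at median depths of 11862, 8386 and 8860 UMIs, beside 10291, 7368 and 8033 UMIs in visceral endoderm-like cells. Tdgf1 was detected in 77.5%, 25.7% and 24.8% of thinned mesoderm-like cells (90.4%, 35.2% and 32.6% not thinned), against 3.58%, 0.41% and 1.10%. Mesp1 was detected in 94.9%, 67.1% and 77.97% (97.3%, 72.0% and 83.3% not thinned), against 7.66%, 4.64% and 5.27%. In epiblast and streak-like cells, Foxb1 was detected in 4.02%, 12.4% and 22.5% (8.97%, 19.95% and 35.9% not thinned), against 0.13%, 0.68% and 1.76%. The median depths of this class were 11474, 8369 and 9682 UMIs.

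**Figure D3:**
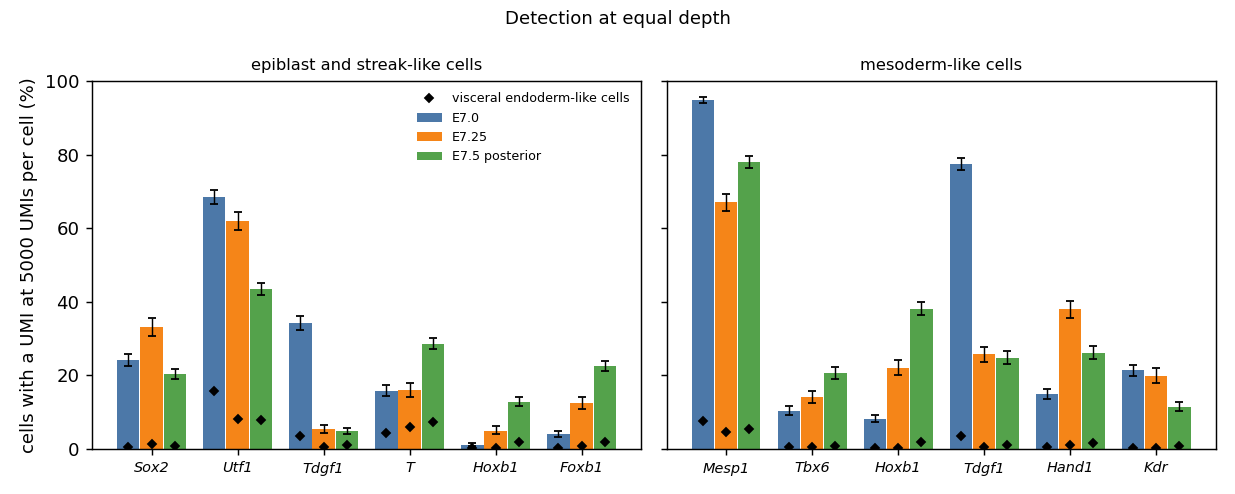
Share of cells with at least 1 UMI of a gene after thinning to 5000 UMIs (percent, vertical axis) in each library, with 95% Clopper-Pearson intervals, beside the share in visceral endoderm-like cells. Hoxb1 in mesoderm-like cells reads 8.24%, 22.0% and 38.1%.

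Xist marks cells with an inactive X chromosome and Y-linked transcripts mark male cells. Xist alone was found in 34.8% of cells at E7.0, 50.7% at E7.25 and 64.7% at E7.5 posterior, and Y-linked UMIs alone in 34.0%, 20.1% and 14.6%. With 2 UMIs required these were 31.2%, 42.9% and 58.4% for Xist and 16.55%, 6.89% and 6.23% for Y-linked genes. Neither was found in 28.5%, 26.5% and 18.75% of cells, or in 52.0%, 49.7% and 35.05% with 2 UMIs required. These shares were taken without thinning, at unequal depth. Every library thus held cells of both sexes, with different shares of cells called as each. Both kinds were found in 2.69%, 2.71% and 1.96% of kept cells and in 21.3%, 22.2% and 22.1% of predicted doublets. Xist stood at 158 CPM at E7.0 and 395 CPM at E7.5 posterior, and the Y-linked Ddx3y at 17.5 and 8.51 CPM.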

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

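No paired analysis was possible because each group is 1 library. The cause of a change was not tested unless stated. Epiblast and streak-like cells at E7.0, 34.2% as reported, were 30.4% with 500 detected genes at least, 36.9% with 2000, 35.7% with 5% mitochondrial UMIs at most, 36.3% with predicted doublets kept, 41.2% at resolution 2, 38.5% with 4000 variable genes and 44.4% with 50 principal components. They were 36.6% with each library clustered by itself, 35.5% without cell cycle genes, 37.5% with cells thinned before clustering and 21.9% with streak-like cells as their own class. At E7.25 (33.6%) they were 30.8% with 500 genes, 37.0% with 5% mitochondrial UMIs, 32.0% with doublets kept, 39.8% at resolution 2, 31.1% with 50 components and 39.5% with each library by itself. At E7.5 posterior (47.4%) they were 18.8% with 500 genes, where the caudal epiblast-like cells were unnamed, 50.1% with 5% mitochondrial UMIs, 53.8% at resolution 0.5 and 52.8% at resolution 2. They were 50.6% with 4000 variable genes, 45.6% with 50 components, 42.3% with each library by itself and 54.03% without cell cycle genes. Mesoderm-like cells at E7.0 (35.6%) were 31.3% with 500 genes, 38.5% with 2000, 37.3% with 5% mitochondrial UMIs, 33.0% with doublets kept, 31.9% at resolution 2, 31.2% with 4000 variable genes, 25.3% with 50 components and 33.1% with each library by itself. At E7.25 (36.1%) they were 34.6% with 500 genes, 37.9% with 5% mitochondrial UMIs, 31.2% at resolution 2, 38.4% with 50 components, 30.2% with each library by itself and 39.9% thinned. At E7.5 posterior (35.9%) they were 39.6% with 2000 genes, 36.99% with 5% mitochondrial UMIs, 29.2% at resolution 0.5, 27.3% at resolution 2, 32.3% with 4000 variable genes, 37.1% with 50 components, 29.3% without cell cycle genes and 40.4% thinned. For whole libraries, the streak list of E7.25 against E7.0 (-1.29) was -1.53 with TMM factors and -0.91 with no minimum for members. The visceral endoderm list of E7.5 posterior against E7.25 (-1.71) was -3.10 with 5% mitochondrial UMIs, -1.80 with doublets kept, -1.60 with TMM factors, -1.80 as a mean over cells and -2.70 without visceral endoderm-like and trophoblast-like cells. The pluripotency list of E7.5 posterior against E7.0 (-0.64) was -0.73 with TMM factors and -0.45 without mitochondrial and ribosomal protein genes and Malat1, where other members pass the minimum. In epiblast and streak-like cells that list (-0.66) was -0.46 with 500 genes, -0.58 with 2000, -0.55 with doublets kept, -0.55 with each library by itself and -0.73 with TMM factors. Some directions turned. With no minimum for members, mesoderm regulators were 0.084 for E7.5 posterior against E7.25 and 0.45 against E7.0, and the retinoic acid list was -0.083 for E7.5 posterior against E7.25. With 500 detected genes, the pluripotency list in epiblast and streak-like cells was 0.031 for E7.5 posterior against E7.25, and against E7.0 the WNT list was -1.95, Cdx2 -0.46, Meis2 -0.36 and brachyury (T) -1.95. The NOTCH list in mesoderm-like cells for E7.5 posterior against E7.0 was -0.19 at resolution 2, -0.13 with each library by itself and -0.063 without mitochondrial and ribosomal protein genes and Malat1. Of 630 values for list medians, 414 stayed, 208 moved and 8 turned. Of 1960 for named genes, 1482 stayed, 475 moved and 3 turned. A value stayed if it lay within the counting interval of the reported result, and turned if its sign changed. For a list median, the limits used were the medians of its members' own interval limits, which are not an interval of the median. List medians were counted only in whole libraries, epiblast and streak-like cells and mesoderm-like cells, and only if at least 0.3 from 0. Of single genes, only those ranked highest and lowest were counted. Smaller medians were left out, some of them smaller than the TMM shift of -0.24 for E7.25 against E7.0. The few turned values therefore do not show how often small ratios keep their direction. All 72 values for shares of cells with a UMI moved, lower when thinned to 3000 UMIs and higher when not thinned. The 4 alternatives on streak-like cells, the deepest cluster and the clusters with few mitochondrial UMIs were chosen after the data were seen.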

Other observations

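Definitive endoderm forms from the anterior streak and gives rise to the gut. In definitive endoderm and gut-like cells, E7.5 posterior against E7.0, the primitive streak list (8 members, 5 lower and 3 within) had a median log2 ratio of -1.75. This median was not tried under the alternatives. Gsc stood at 20.7 and 198 CPM (log2 ratio -3.26, 95% interval -3.72 to -2.84), Mixl1 at 5.97 and 51.2 CPM, Tdgf1 at 91.8 and 430.1 CPM and the NODAL inhibitor Lefty1 at 2.76 and 51.7 CPM, while brachyury (T) was higher, at 172.2 and 104.9 CPM. Also higher were Gpx2, a glutathione peroxidase of gut epithelium, at 86.8 and 12.1 CPM (2.84, 2.49 to 3.19), the signalling peptide Apela at 147 and 31.5 CPM and the glucose transporter Slc2a3 at 791 and 217 CPM. Slc2a3 ranged from 1.45 to 2.56 over the alternatives. With each library clustered by itself Tdgf1 was -2.96 in place of -2.23, Lefty1 -5.07 in place of -4.23 and Mixl1 -3.69 in place of -3.10, and with at least 2000 detected genes Gsc was -3.89. E7.25 against E7.0 showed Gpx2 at 83.6 and 12.1 CPM, Gsc at 43.4 and 198 CPM (-2.19, or -2.79 with each library by itself) and Mixl1 at 9.58 and 51.2 CPM. Spink1, of the visceral endoderm list, was also higher at E7.5 posterior than at E7.0 (376.5 and 124.1 CPM, 1.60, or 4.81 with each library by itself and 0.19 with at least 2000 detected genes). At E7.25 against E7.0, 3 of 6 measured genes of that list were at least 2-fold higher and 3 within, and the imprinted gene H19 had a log2 ratio of 2.28, or 4.87 with each library by itself and 1.38 with at least 2000 detected genes, so the visceral endoderm content of this class may differ between libraries. These are 735, 181 and 244 cells at E7.0, E7.25 and E7.5 posterior.

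The node organises the axis and its cells bear cilia. In node and notochord-like cells (255 at E7.0 and 231 at E7.5 posterior) Hoxb1 (64.0 and 1.71 CPM, log2 ratio 5.22, 3.96 to 6.88), Cdx2 (94.5 and 2.74 CPM, 5.11, 4.09 to 6.35), Hes7 (54.2 and 6.16 CPM) and Foxb1 (57.3 and 7.19 CPM) were higher at E7.5 posterior. The neuropeptide gene Gal stood at 231 and 11.3 CPM. Pou3f1 (7.92 and 55.4 CPM) and Zic2 (30.5 and 119 CPM) were lower. The ratio of Pou3f1 ranged from -2.96 to -1.14 over the alternatives. With each library clustered by itself the log2 ratios were 6.27 for Hoxb1, 5.89 for Cdx2, 4.05 for Hes7, 5.17 for Gal and 3.67 for Foxb1, in place of 5.22, 5.11, 3.14, 4.35 and 3.00.

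The stage test and the test of all short genes here were chosen after the result was seen, and the other tests before. In epiblast and streak-like, mesoderm-like, definitive endoderm and gut-like and visceral endoderm-like cells, 96 genes were at least 1.5 times lower at E7.25 than in both other libraries, and 61 were higher. The 96 genes had a median longest transcript of 1308 bases, against 2767 to 3760 in random draws, so lower capture of short transcripts could add to this pattern. The draws were not matched on expression. The 61 higher genes had a median of 2631 bases, also under the 3222 of all genes tested. Median GC content was 48.1% in the lower genes, 55.6% in the higher genes and 49.4% in genes tested. For E7.25 against E7.0 in epiblast and streak-like cells, the median log2 ratio was -0.36 for genes with transcripts up to 600 bases (55 genes) and 0.13 for those over 4000 bases, and against E7.5 posterior -0.19 and 0.08. All genes no longer than 1308 bases, the 96 included, had medians of -0.22 to 0.0 over these classes and both other libraries. Their lowest lower quartile was -0.59. The 96 genes, which were chosen for being lower, had medians of -1.11 to -0.86 in the same comparisons. Most genes as short thus moved less than these 96. Length as the whole cause stays undecided, since the 96 were chosen for low ratios and the lowest lower quartile reached a 1.5-fold drop. Length as a part also stays open. Of the 96 genes, 26.0% share a stretch of 60 bases near their 3' end with another gene, against 6.4% of genes tested. The 61 higher genes shared such a stretch about as often, among them Actb, Tuba1b, Rps15 and Cdc34. A difference in how shared reads were counted may add to the pattern, but the stretch does not set the lower genes apart from the higher ones. The 71 of the 96 genes without it were also short (median 1448 bases). In trophoblast-like cells the median log2 ratio of the 96 genes was -1.04 for E7.25 against E7.0, with 88 of 88 measured under 0. A stage difference common to all tissues cannot be told apart from a library difference on this value.

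The free RNA test, the random placement, the depth of the richest cells and the count in the deep cluster here were chosen after the result was seen, and the multiplet test before. Visceral endoderm transcripts were higher in mesoderm-like cells of E7.25. Outside a deep cluster of 96 cells, the median ratio of 13 such transcripts in mesoderm-like over epiblast and streak-like cells of E7.25 was 1.03, with 1 over 1.5, which could come from free RNA spread over all droplets. The tenth of mesoderm-like cells richest in these transcripts held 56.9% of them, against a median of 13.1% when they fell on cells at random, and the deep cluster held 51.3% of them with 16.2% of all UMIs of the class. Of these richest cells (180), 51 were of the haemato-endothelial-like cluster, 42 of the deep cluster and 34 of the other extraembryonic mesoderm-like cluster. Their median depth was 8086 UMIs, against 8444 in the other cells and 7100 to 7886 for the richest 180 under random placement. Apoe weighs most in these sums, at 488 CPM in mesoderm-like cells of E7.25, with Apoc2 next at 122 CPM. It is also the transcript over 1.5, at 414.5 CPM outside the deep cluster and 273.7 CPM in epiblast and streak-like cells. Droplets with more than 1 cell may hold part, but the concentration cannot separate them from expression in some mesoderm-like clusters. Both sources and expression by mesoderm itself stay open.

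Both tests here were chosen after the result was seen. Of 17 measured histone genes, 14 were at least 2-fold lower at E7.5 posterior than at E7.0 (median log2 ratio -1.52), with medians of -1.46 in epiblast and streak-like and -1.62 in mesoderm-like cells. The S phase list, at 0.17, argues against fewer cells in S phase. All 84 genes with transcripts no longer than the median of these histone genes, histone genes included, had a median of -0.15 and a lower quartile of -0.26, which argues against transcript length alone. Most replication-dependent histone messages lack a poly(A) tail, so priming of such messages may differ between libraries, and this and a difference between stages or regions were not tested.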
